A study of Mus musculus with 2 samples.

How the data were processed

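The series holds 2 single-cell libraries of the 4th mammary gland of mice, 1 from Gpm6a-deleted and 1 from wild-type animals, and each label describes sorted DAPI-negative cells of 3 littermates. The deposited matrices hold counts of unique molecular identifiers (UMIs) for 32285 genes per barcode, from 10x Genomics 3′ libraries. All values were whole numbers of at least 0, and no barcode had fewer than 500 UMIs, so the barcodes had already been filtered on depth. The submitters' processing notes name Cell Ranger 5.0.1, Seurat 3.2.0 and the build mm10. The files carry no cell types, so cells were classed anew. Gene positions and transcript lengths were taken from GENCODE M21 on GRCm38, which holds 99.6% of the gene identifiers in the files.

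Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. This kept 10907 of 11442 KO and 10984 of 12291 WT barcodes. Scrublet, as built into scanpy 1.11.5, was run on each library with an expected rate of 0.8% per 1000 barcodes and its automatic threshold, and the 437 KO (4.01%) and 654 WT (5.95%) barcodes it called doublets were removed. The 10470 KO and 10330 WT cells left are those analysed. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components by an exact decomposition, each cell was joined to its 20 nearest neighbours weighted by shared neighbours, and both libraries were clustered together by the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, with no correction between libraries.

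A cluster took the name of a class from markers of 21 cell types that were fixed before the data were examined. A marker counted when it was at least 2-fold above the other cells and had a UMI in at least 10% of the cluster's cells. A name needed at least 3 markers, at least 50% of the type's markers, a mean log2 fold of at least 1, a lead of at least 0.5 over the next type, and no more markers of another type than of its own among the 10 top genes. A cluster whose median UMI count was under the sample's median divided by 3 also needed a marker of its own there. These limits on naming were revised after the clusters had been seen, while the markers were kept. They left 10 of 32 clusters without a name, holding 10.5% of KO and 23.5% of WT cells. Clusters with at most 5% of their cells from 1 library were set apart as clusters of 1 library. Where the text says epithelial cells without naming a class, clusters 6, 7 and 20 were counted with the 3 epithelial classes.

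Within a class, UMIs were summed per library and divided by the class total to give counts per 1000000 (CPM). Ratios are log2 of KO over WT with 1 CPM added to each. Each library is 1 replicate, so no test was made and no p-value is given. Values of CPM carry exact Poisson intervals and shares exact Clopper-Pearson intervals at 95%, and the intervals of list medians come from 200 Poisson redraws of the counts. All of them cover counting error only. Where a count was 0, the limit is 3 counts. Expression was compared in 13 groups of at least 100 cells per library, 4 of them (basal, luminal progenitor, hormone-sensing luminal, fibroblast) as main classes.

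The lists compared were 27 sets of genes written down before the data were examined, with ribosomal protein genes and mitochondrially encoded genes as 2 further lists. A list's value is the median log2 ratio of its members with at least 20 UMIs over both libraries, placed among 10000 random lists of the same size matched on level in 20 bins. Genes named in the text follow a rule fixed before the data were examined: in each main class the 10 highest and the 10 lowest log2 ratios, and in each other group the 3 highest and the 3 lowest, among genes with at least 50 CPM in the higher library, at least 100 UMIs over both, and a level of at least 0.5 times that in all other cells. Ribosomal protein, mitochondrial, haemoglobin, Gm and Rik genes were not named. The members with the highest and lowest value of a list may be named too. The 6 genes of high endothelial venules were written down before their values were looked at, but after Glycam1, Ccl21a and Ubd had been seen. Other genes, such as Slpi, were chosen after their values were seen. Cycling cells were those with a UMI in at least 2 of the G2/M genes after thinning to 2000 UMIs, with shallower cells left out.

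The alternatives fixed before the data were examined were all deposited barcodes, at most 5% mitochondrial UMIs, doublets kept or removed up to the expected rate, Leiden resolutions 0.5 and 2, each library clustered alone, cells classed one by one by their highest marker score, scaling by TMM factors (edgeR 4.0.16 in R 4.3.3), pseudocounts of 0.1 and 5 CPM, thinning to 2000 or 1000 UMIs or none, the mean over cells of CPM per cell, list members with at least 100 UMIs, and at least 3 G2/M genes. Others were added after seeing the data: leaving out cluster 30 or all clusters of 1 library, adding cluster 6 to basal cells or cluster 10 to fibroblasts, and taking each ratio relative to the gene's median ratio in the other classes.

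The steps were tested on simulated data with counting error only, in which 200 genes of each main class were shifted 1.5-, 2- or 4-fold. Of these, 100% came out in the right direction, and the 95% intervals held the true ratio for 92.4% to 98.5% of them. Of 20 unshifted lists per class, 0 to 2 fell outside the middle 95% of random lists, and all 20 lists shifted 1.5-fold did. The simulation holds no differences between animals. Computations used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.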

Results

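RNA of single cells was counted in the 4th mammary gland of virgin female mice, 6 to 8 weeks old. They carried a deletion of Gpm6a (KO) or were wild type (WT), and the labels do not give the deleted part. Per the labels, living (DAPI-negative) cells were sorted from 3 littermates of each genotype, and 1 library was deposited per genotype. The labels call them total primary mammary epithelial cells, although stromal and immune cells were present, and do not say whether cells of the 3 animals were pooled. The KO library held 11442 barcodes with 139757797 UMIs (median 9396 per barcode), and the WT library 12291 barcodes with 160026788 UMIs (median 10168). After filters and removal of called doublets, 10470 KO cells (median 9521 UMIs) and 10330 WT cells (median 11130.5 UMIs) were analysed. Clustering both libraries together gave 32 clusters, of which 22 were named as 14 cell classes from marker genes. Each class name below means cells like that type. Levels are counts per 1000000 UMIs of a class (CPM), and brackets hold 95% intervals, exact Poisson for CPM and exact Clopper-Pearson for shares, which cover counting error only. With 1 library per genotype, no difference below has a replicate check, and no test was made. The comparisons, gene lists, markers and the rule for naming genes were fixed before the data were examined.

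Gpm6a encodes the membrane glycoprotein M6a, known best from neurons. In the files it is ENSMUSG00000031517, a protein-coding gene on the + strand of chromosome 8 from 54954843 to 55060871 in GENCODE M21 (GRCm38). Over all analysed cells it had 29 UMIs in the KO library, 0.225 (0.151 to 0.323) CPM, and 284 UMIs in the WT library, 1.95 (1.73 to 2.19) CPM. Of the WT UMIs, 187 (65.8%) lay in cluster 30, which held 57 WT cells and 1 KO cell and was led by the mesothelial genes Upk3b, Msln and Wt1. In its WT cells, Gpm6a reached 337 (291 to 389) CPM, with a UMI in 38.6% (26.0 to 52.4%) of cells. Vascular endothelial cells held 22 KO and 20 WT UMIs, 7.21 (4.52 to 10.9) against 5.71 (3.49 to 8.82) CPM. Mast cells held 3 against 9 UMIs, 10.1 (2.08 to 29.4) against 33.6 (15.4 to 63.8) CPM. Counts near the 3′ end that may lie outside the deleted part check nothing about the deletion. Without cluster 30, the levels were 0.225 (0.151 to 0.323) and 0.668 (0.541 to 0.815) CPM, so this cluster of a single library carries most of the difference in level. The log2 ratio was -1.27 over all cells and -0.45 without cluster 30 with 1 CPM added, and -2.66 over all cells with 0.1 CPM added, so at these levels its size rests on the amount added.

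In epithelial cells, Gpm6a had a UMI in 0 of 3239 KO cells, which allows up to 0.0926%, and in 7 of 3131 WT cells, 0.224% (0.0899 to 0.460%). T cells, which should lack it, held it in 0 of 712 KO cells (up to 0.421%) and in 0.356% (0.00901 to 1.97%) of 281 WT cells, at median depths of 4765 and 5306 UMIs against 13060 and 11370 in basal cells. This background rests on 1 WT T cell, with an interval up to 1.97%, and on shallower cells. It cannot tell whether the epithelial share in the WT library lies above background. Of the 40 WT epithelial UMIs, 34 lay in 3 cells that also held 46 to 89 UMIs of 10 leading genes of cluster 30, among them Upk3b, Msln and Lrrn4. The other 4 cells with Gpm6a held at most 5, and the 3124 WT epithelial cells without it a median of 0. Luminal progenitors had no Gpm6a UMI in either library, with limits of 0.682% of KO and 1.2% of WT cells.

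**Figure D1:**
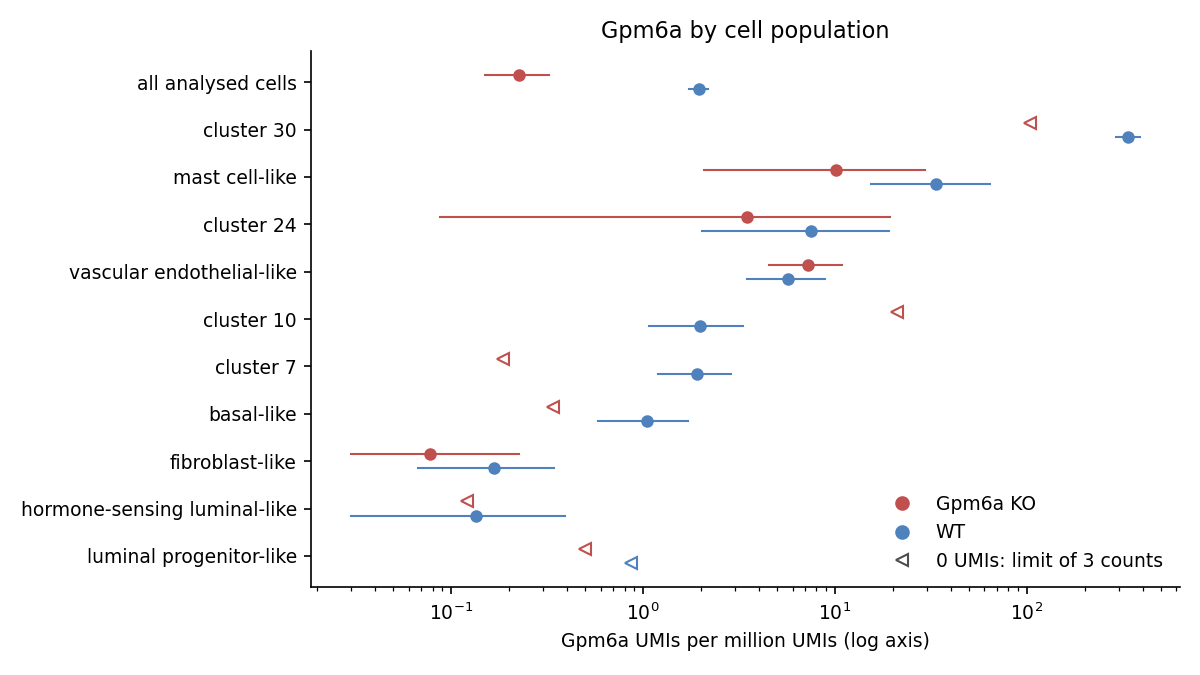
Gpm6a UMIs per 1000000 UMIs (log axis) by cell population in the KO and WT libraries, with points for levels, lines for exact 95% Poisson intervals and open triangles for the limit of 3 counts where no UMI was seen. Cluster 30 in the WT library stands highest, at 337 CPM, while vascular endothelial cells held 7.21 CPM in the KO and 5.71 CPM in the WT library.

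Of the cells in the 3 named epithelial classes, basal cells, the contractile outer layer marked by Krt5 and Krt14, made up 24.9% (23.2 to 26.8%) against 42.7% (40.6 to 44.9%) in the KO and WT libraries. Luminal progenitors, marked by Elf5 and Aldh1a3, made up 19.5% (17.9 to 21.2%) against 11.8% (10.5 to 13.3%), and hormone-sensing luminal cells, marked by Prlr and Esr1, made up 55.6% (53.5 to 57.6%) against 45.5% (43.3 to 47.6%). The lower basal share in the KO library also held with cluster 6, which has basal markers beside Il17b, Col9a1 and Wif1, added to the 3 classes and counted as basal: 36.7% against 55.1%. Cluster 7, with Aldh1a3 and Elf5 beside hormone-sensing markers, held 4.31% against 3.07% of all cells, and cluster 20, led by the dividing-cell genes Hmmr and Ube2c, 1.06% against 1.09%. Shares are of sorted DAPI-negative cells and depend on how each cell type survives digestion. When each library was clustered alone, the luminal progenitor share turned to 16.5% against 19.2%. The class then held 447 KO and 563 WT cells, in place of 440 and 250. The WT class thus gained many cells that joint clustering had placed elsewhere, while the KO count hardly changed. The class may therefore not hold like cells in both libraries, and the direction of this share rests on how cells are grouped.

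Of all analysed cells, fibroblasts with Col1a1 and Dcn were the most numerous, 43.7% (42.8 to 44.7%) against 36.8% (35.9 to 37.7%). Among their 5 clusters, cluster 3, with Pi16 and Dpp4, held 24.6% (23.4 to 25.9%) against 19.7% (18.4 to 21%) of fibroblasts, cluster 0 28.2% (26.9 to 29.6%) against 32.2% (30.7 to 33.7%) and cluster 16 3.43% (2.92 to 4%) against 4.89% (4.23 to 5.63%). Cluster 4 held 20.3% against 20.9% and cluster 2 23.5% against 22.3%. Cluster 4 was led by Vit, Clec11a and C2, with Il6, Ccl8 and the interferon gene Ifit1 further down its leading genes. Its median depth was 5071 UMIs, against 9731 to 11312 in the other fibroblast clusters. T cells made up 6.8% (6.33 to 7.3%) against 2.72% (2.42 to 3.05%), B cells 3.72% (3.37 to 4.11%) against 1.34% (1.12 to 1.58%) and natural killer cells 1.28% (1.07 to 1.51%) against 0.707% (0.554 to 0.888%). Dendritic cells made up 4.65% against 3.49% and macrophages 2.09% against 2.05%. Among immune cells alone, T cells were 35.2% against 24.4% and macrophages 10.8% against 18.4%. Pericytes or smooth muscle cells made up 1.69% (1.45 to 1.96%) against 4.01% (3.64 to 4.4%), vascular endothelial cells 3.13% against 3.43%, and skeletal muscle cells, which come from tissue beside the gland, 0.0573% against 0.61%. The pericyte or smooth muscle class was cluster 12 alone, with 5 of 7 markers and Pln and Myocd among its leading genes. It left out the unnamed cluster 24, which had 7 of 7 of these markers. Neutrophils made up 0.353% against 0.542% and mast cells 0.392% against 0.29%. At most 5% mitochondrial UMIs, with the cells clustered and named anew, the fibroblast share turned to 45.8% against 47.4%. The class then held 4575 KO and 4338 WT cells, in place of 4578 and 3802. A stricter filter adds no cells, so the WT gain came from regrouping. With each library clustered alone the ratio of T cell shares was 5.43 in place of 2.5. There, T cells numbered 760 in the KO and 138 in the WT library, in place of 712 and 281, so many WT cells had left the class.

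The 10 unnamed clusters, which the marker limits kept out of the classes, held 10.5% (9.95 to 11.1%) against 23.5% (22.7 to 24.4%) of the cells. Of these, 5 clusters lay almost wholly in the WT library, with 0.181% of KO and 10.6% of WT cells. They may be that library and not a cell type, least so cluster 18 and cluster 30, which was led by mesothelial genes. Cluster 10, with Rspo3, Rxfp2 and Myoc beside 4 of 7 fibroblast markers, held 15 KO and 647 WT cells. Cluster 18, with the lipid and keratinocyte genes Cst6, Olah, Krt79 and Fa2h, held 0 KO cells, which allows up to 0.0287%, and 295 WT cells. For it, 5 KO against 300 WT cells (1.67%) of any cluster held its leading genes at the level of its own cells. This argues against a shared type split between the libraries by a shift that leaves these genes in place. The genes were chosen from these WT cells, so a shift that lowered them is not excluded. Cluster 19 was led by the cell-cycle genes Pclaf, Ccna2 and Top2a and held 0.430% of KO and 2.19% of WT cells at median depths of 14734 and 1998 UMIs, so its cells were unlike in depth between the libraries. Cluster 24, with Rgs5, Kcnj8 and Ccl19 among its leading genes, held 0.554% and 0.871%. It had 6 of 6 Schwann markers (mean log2 fold 5.74) and 7 pericyte or smooth muscle markers (4.33). With cluster 10 added, the fibroblast shares were 43.9% and 43.1%.

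**Figure D2:**
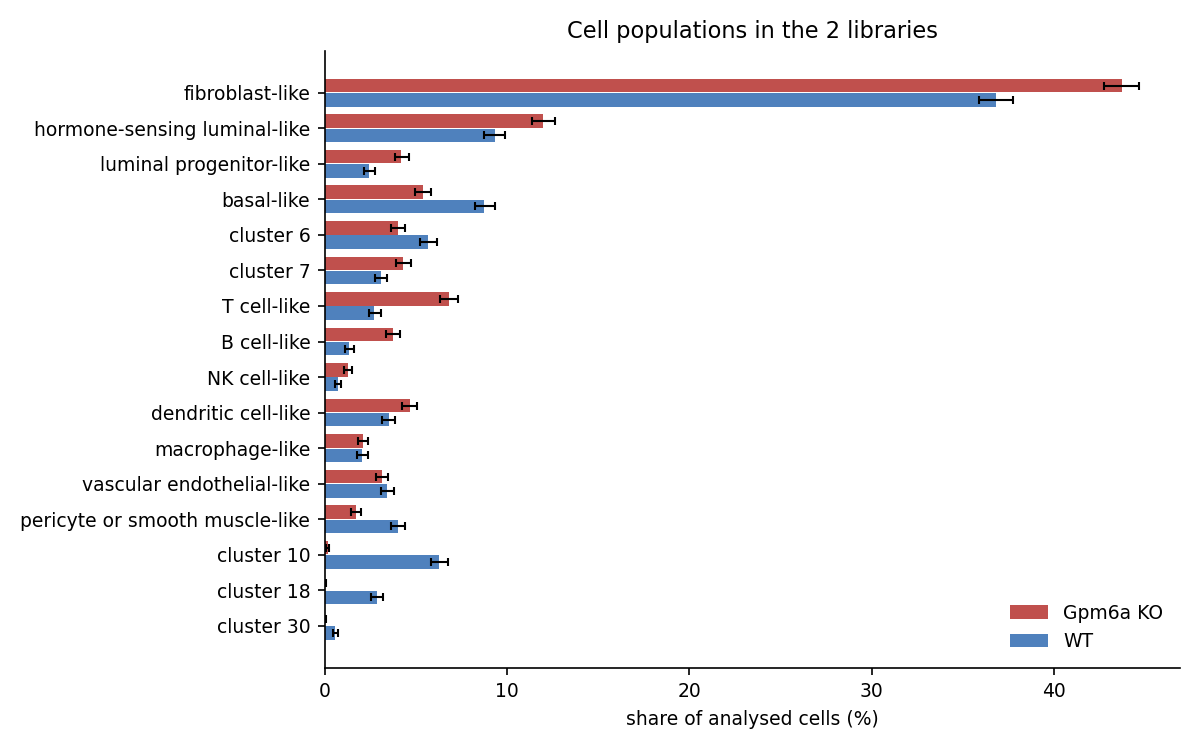
Share of analysed cells (%) in 16 populations of the KO and WT libraries, with bars for shares and lines for exact 95% Clopper-Pearson intervals. Basal cells stood at 5.38% in the KO and 8.75% in the WT library, T cells at 6.8% and 2.72%, and cluster 18 at 0% and 2.86%.

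In basal cells, Tcim, a small transcriptional regulator, was higher in the KO library at 153 (145 to 162) against 48.9 (45.3 to 52.6) CPM. Also higher were Sfn, which encodes 14-3-3 sigma, at 2740.3 against 1263 CPM, the urokinase receptor gene Plaur at 255 against 111 CPM, the TWEAK receptor gene Tnfrsf12a at 749 against 369.5 CPM, the surface protein gene Tm4sf1 at 1477 against 730.4 CPM, Lgals1 at 664 against 339 CPM and the mitochondrial import gene Timm23 at 156 against 78.1 CPM. The keratin gene Krt17 was at 4559 against 2434 CPM, while the transcription factor gene Trp63 was lower at 74.6 against 92.7 CPM. The water channel gene Aqp3 was at 58.7 against 22.9 CPM, with a log2 ratio of 1.32, and 0.67 when cells were classed one by one. Lower in the KO library were the linker histone gene Hist1h1b at 47.2 (42.8 to 52) against 153 (147 to 159.7) CPM, the amino acid transporter gene Slc38a2 at 777 against 1759.7 CPM, the choline kinase gene Chka at 126 against 300.4 CPM, the histone methyltransferase gene Kmt5b at 54.7 against 125 CPM and Ddit4 at 27.5 against 66.7 CPM. Hist1h1b, a leading gene of basal cluster 25, had a UMI in 45 of 563 KO and 116 of 904 WT cells. Of its UMIs, 34.6% in the KO and 22.5% in the WT library lay in 5 cells. The ratio of Ddit4 moved from -1.25 to -0.66 after thinning to 2000 UMIs per cell.

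Among gene lists in basal cells, the 15 G2/M genes had a median log2 ratio of -0.49 (-0.57 to -0.35, percentile 0.0) and none was above 0, from Cdca8 at -0.02 to Top2a at -0.96. Each percentile is the list's place among 10000 random lists matched on level but not on transcript length, as a description of these libraries. The Notch list stood at -0.43 (-0.55 to -0.34, percentile 0.04), with Hes1 at 162 against 369 CPM and the Notch ligand gene Jag1 the other way at 194 against 129 CPM. Genes linked to mammary stem cells stood at -0.42 (-0.47 to -0.17, percentile 0.0), with Procr lowest at 2.48 against 8.41 CPM and Snai2 highest at 221 against 158 CPM. Adipogenic genes stood at -0.75 (-1.14 to -0.43, percentile 0.0), mostly from low counts such as Fabp4 at 9.13 against 29.5 CPM. The fibroblast gene Col1a1 stood at 45.1 against 83.8 CPM in these basal cells, so low counts of stromal and fat genes are within reach of free RNA. Keratins and contractile genes stood at 0.09 and basement membrane genes at -0.25 (-0.30 to -0.18, percentile 0.22). After thinning to 2000 UMIs, the G2/M median was -0.07. The basal class includes cluster 25, whose leading genes were cycle genes beside Serpinb11, Lbhd2 and Shisa8, which are leading genes of cluster 6 too. Relative to the other classes, a reference within reach of free RNA for genes that few classes express, the Notch median was -0.05, with Hes1 lower in all 13 cell groups, and the medians of G2/M and stem-cell genes were -0.31 and -0.21.

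In luminal progenitors, 12 of 13 measured interferon-stimulated genes were higher in the KO library, with a median log2 ratio of 0.77 (0.48 to 1.07, percentile 100). Ifit3 stood at 15.3 against 3.73 CPM and the tetherin gene Bst2 at 73 (66.3 to 80.2) against 28.4 (23.1 to 34.6) CPM, while Ifit1 was lower at 10.5 against 21.5 CPM. MHC class I and antigen-processing genes stood at 0.39 (0.30 to 0.59, percentile 99.9), led by the immunoproteasome gene Psmb9 at 22.8 against 7.17 CPM. MHC class II genes stood at 0.61 (0.27 to 0.96, percentile 99.5) at low levels, such as H2-Ab1 at 9.17 against 4.01 CPM. When cells were classed one by one, the interferon median was 0.16 and the MHC class II median turned to -1.65. The chemokine gene Cxcl10 was at 50.2 (44.7 to 56.2) against 11.5 (8.19 to 15.6) CPM, but 1 cell held 56.5% of its KO and 1 cell 57.5% of its WT UMIs, and its ratio turned from 2.04 to -0.21 with cells classed one by one.

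The heat shock gene Hspa1a was also higher in KO luminal progenitors, at 75.7 (68.9 to 83) against 21.5 (16.9 to 27) CPM, with 1 cell holding 21.4% of the KO UMIs and a ratio that ran from 0.42 with cells classed one by one to 2.90 after thinning (1.77 as counted). Also higher were the mitochondrial folate enzyme gene Mthfd2 at 63.3 against 28.4 CPM (log2 1.13, and 2.23 after thinning), the transcription co-regulator gene Cited4 at 68.8 against 34.1 CPM, the neurotrophic factor gene Nrtn at 85.5 against 44.7 CPM and the peptide transporter gene Slc15a2 at 101 against 55.9 CPM. Phpt1, Tmem14c and Cmc1 followed with log2 ratios of 0.89, 0.82 and 0.80. Lower were the integrin gene Itgb6 at 32.2 (27.8 to 37) against 79.1 (70.1 to 89) CPM, the growth factor gene Pdgfb at 34.7 against 83.1 CPM, the actin-severing gene Dstn at 943 against 2194 CPM and the helicase gene Ddx21 at 94.8 against 229.9 CPM. For Pdgfb, 5 cells held 18.75% of the KO and 41.7% of the WT UMIs. Luminal progenitor genes as a list stood at -0.02, with Elf5 at 174 against 112 CPM and Trf at 286 against 426 CPM. Milk genes stood at -0.30 (-0.43 to -0.11, percentile 1.76), with Lalba at 70.7 against 144 CPM, and TGF-beta and BMP genes at -0.35 (-0.45 to -0.18, percentile 0.13), with Id3 at 67 against 117 CPM. Relative to the other classes, the milk median turned to 0.10, the TGF-beta and BMP median was -0.15, and Slc15a2 turned to -2.12, where its reference is weak at 10.1 CPM in other cells.

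In hormone-sensing luminal cells, the calcium-binding protein gene Tesc was higher in the KO library at 72.1 (68.8 to 75.5) against 34.6 (32.2 to 37.1) CPM, Ramp1, part of the CGRP receptor, at 50.3 (47.5 to 53.1) against 24.3 (22.3 to 26.4) CPM, and Rnaset2a at 68.5 against 33 CPM. Bst2 stood at 119 against 70.1 CPM, the MHC class I gene H2-T23 at 269 against 161 CPM, and Dnajc12, Nt5c, Erh and Rnaset2b at log2 ratios of 0.70, 0.70, 0.76 and 0.79. Sbp, which encodes a secretory protein, had 60.3 against 13.4 CPM, but 1 cell held 73.5% of its KO UMIs. Lower were the iodide transporter gene Slc5a5 at 71.7 (68.4 to 75.1) against 169 (164 to 175) CPM, the glutathione peroxidase gene Gpx3 at 431 against 959 CPM, the N-myristoyltransferase gene Nmt1 at 99.8 against 235 CPM, the Golgi gene Golga2 at 25.4 against 54.9 CPM and the cytokine gene Csf3 at 28.9 against 63 CPM. This class was itself led by the immune enzyme gene Ido1. Relative to the other classes, Bst2 turned to -0.08 and Rnaset2b to -0.18.

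All 13 measured NF-kB and inflammatory genes were lower in KO hormone-sensing cells, with a median of -0.52 (-0.63 to -0.38, percentile 0.0), from Cxcl5 at -0.18 to Csf3 at -1.10. Hormone receptor and hormone-response genes stood at -0.04 (-0.07 to 0.00, percentile 31.6), with Pgr at 223 against 330.4 CPM and Wnt4 at 213 against 169.9 CPM. Interferon-stimulated genes stood at 0.19 (0.09 to 0.33, percentile 99.4) and MHC class II genes at 0.38, a direction that turned to -0.05 with doublets kept. Keratins and contractile genes of basal cells stood at 0.96, with Actg2 at 5 against 1.25 CPM, which turned to -1.35 with doublets kept and to -0.79 with cells classed one by one. Fibrillar collagen and matrix genes stood at -0.86 (-0.97 to -0.73, percentile 0.0), with Dcn at 21.1 against 67.7 CPM. Col1a1 had a UMI in 30.1% (27.6 to 32.7%) of KO and 47.4% (44.2 to 50.6%) of WT hormone-sensing cells at median depths of 16910 and 19930 UMIs, and in 20.4% (17.5 to 23.5%) and 33.8% (28.3 to 39.7%) of T cells, which should lack it, at 4765 and 5306. These matrix counts are therefore within reach of free RNA. Relative to the other classes, the NF-kB median was -0.27 and the interferon median 0.03.

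In fibroblasts, Bst2 was higher in the KO library at 219 (215 to 224) against 107 (104 to 110.2) CPM and the interferon gene Ifi27l2a at 751 (742 to 759) against 399 (393 to 405) CPM. Interferon-stimulated genes as a list stood at 0.25 (0.20 to 0.29, percentile 99.9), with 11 of 14 above 0 and Stat2 lowest at -0.41. This list was not higher in every class: it stood at -0.11 (-0.28 to 0.16) in basal cells, -0.48 (-0.63 to -0.28) in T cells and -0.28 (-0.33 to 0.01) in dendritic cells, against 0.73 (0.17 to 1.07) in B cells. The stress-response gene Nupr1 stood at 839 against 432 CPM, Mthfd2 at 72.5 against 37.1 CPM, the selenoprotein genes Selenom and Selenow at 352 against 183 CPM and 619 against 338 CPM, H2-T23 at 112 against 61.6 CPM and the translation repressor gene Eif4ebp1 at 149 against 85.1 CPM. Arf5 and Tmem223 had log2 ratios of 0.85 and 0.81. Lower were Ubtd2 at 45.1 against 98.1 CPM, the endoplasmic reticulum chaperone gene Hyou1 at 36.8 against 68.7 CPM, the sphingomyelinase gene Smpd3 at 148 against 264 CPM, and Ddx21 and Taf1d at -0.99 and -0.91 on the log2 scale. The chemokine gene Cxcl9 was at 33.2 against 60.0 CPM, with 1 cell holding 24.5% of its KO and 26.9% of its WT UMIs, and its ratio moved from -0.84 to -0.22 with cells classed one by one. Fibrillar collagen and matrix genes stood at -0.20 (-0.21 to -0.20, percentile 1.24), from Bgn at -0.47 to Fn1 at 0.12. Relative to the other classes, Nupr1 turned to -0.04, Smpd3 to 0.18, Ddx21 to 0.14 and Taf1d to 0.03, and the interferon median was 0.15.

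In all 4 of these classes, 19 of 20 nuclear genes of the respiratory chain were higher in the KO library. Their median log2 ratios were 0.26 (0.24 to 0.30, percentile 99.5) in basal cells, 0.27 (0.23 to 0.32, percentile 99.8) in luminal progenitors, 0.25 (0.22 to 0.26, percentile 99.6) in hormone-sensing cells and 0.42 (0.39 to 0.45, percentile 100) in fibroblasts. Uqcrb, of complex III, stood at 535 against 382 CPM in hormone-sensing cells, and Atp5b, of the ATP synthase, was the exception, at -0.10, -0.17, -0.09 and -0.23. Mitochondrially encoded genes went the other way, at -0.43, -0.52, -0.47 and -0.29, with mt-Atp8 lowest in each. Ribosomal protein genes stood at 0.04, 0.27, 0.16 and 0.44, with Rps29 lowest in each. The snoRNA host gene Snhg9 was lower in the KO library at log2 ratios of -2.34, -2.36, -2.56 and -2.17, and the mitochondrial leucyl-tRNA synthetase gene Lars2 at -1.66, -1.66, -1.31 and -1.32. Tsix, antisense to Xist, stood at -1.73, -2.14 and -1.87 in the epithelial classes. The dynein gene Dync1i2 stood at -1.13, -1.16, -1.15 and -0.91, and the unplaced genes AC149090.1 and AC160336.1 at -2.74 in basal cells and -2.02 in fibroblasts. Taken relative to each gene's median ratio in the other classes, the respiratory chain medians were 0.05, -0.03, -0.04 and 0.12, so the respiratory chain difference is shared by the classes. On that scale AC149090.1 stayed at -1.07 in basal cells, and ribosomal protein genes stood at 0.24 in fibroblasts and turned to -0.21 in basal cells.

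**Figure D3:**
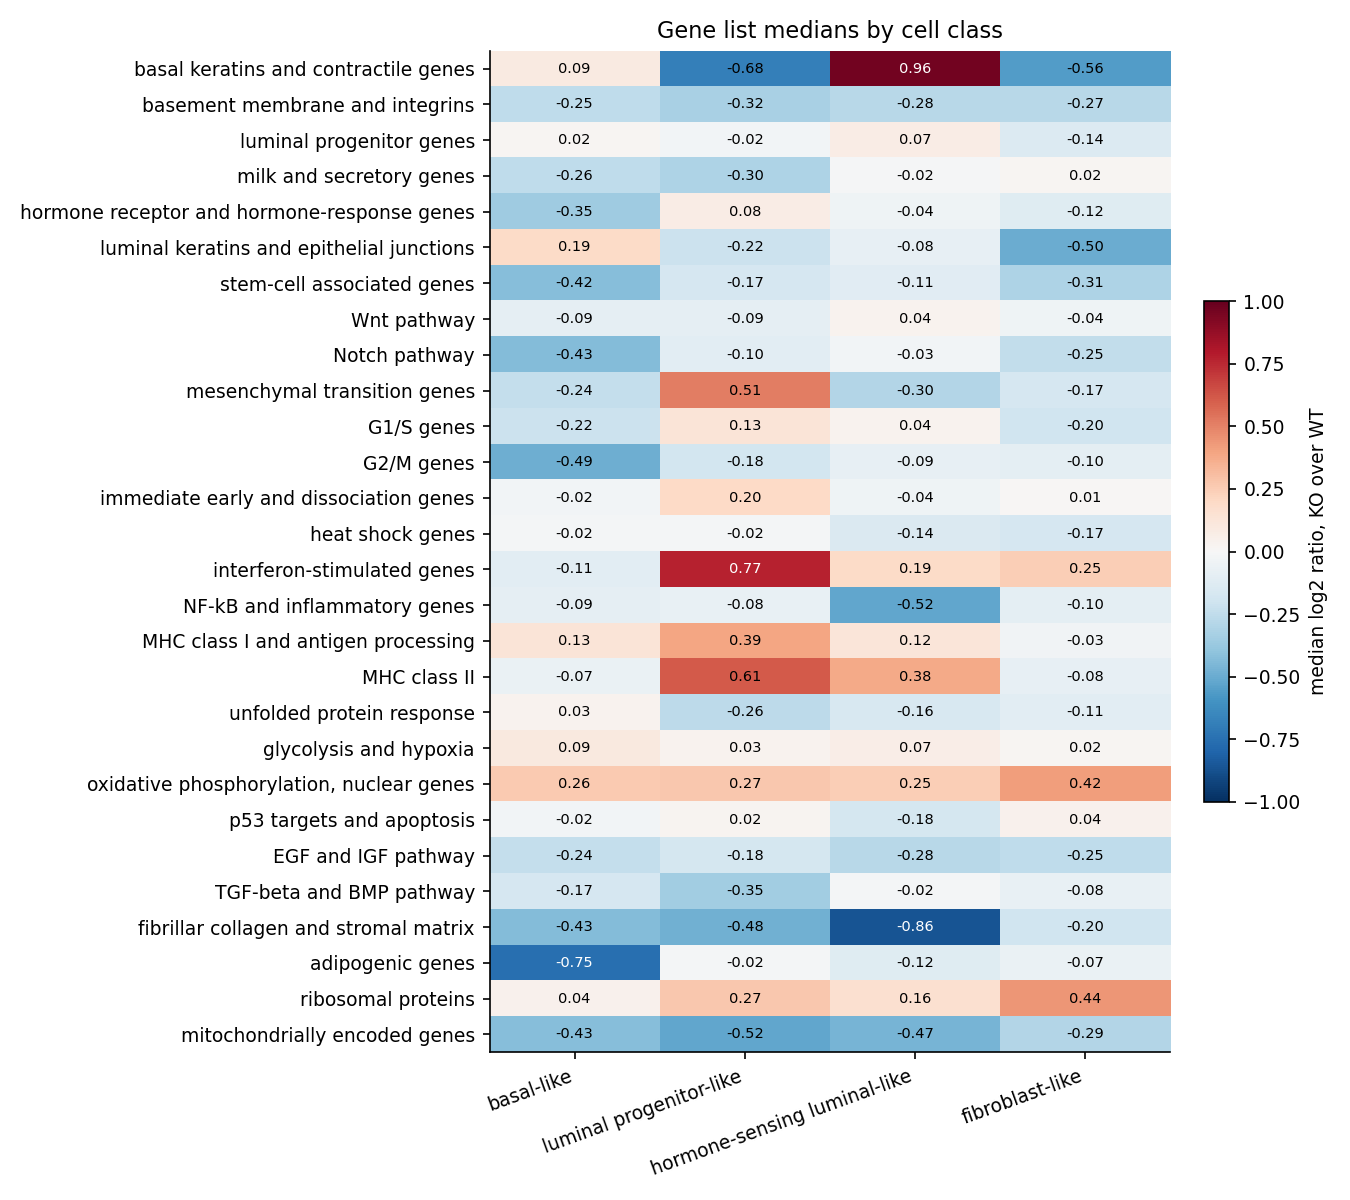
Median log2 ratio of KO over WT for each gene list (vertical axis) in 4 cell classes (horizontal axis), by colour and number. Respiratory chain genes stood between 0.25 and 0.42 and mitochondrially encoded genes between -0.52 and -0.29 in the 4 classes.

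**Figure D4:**
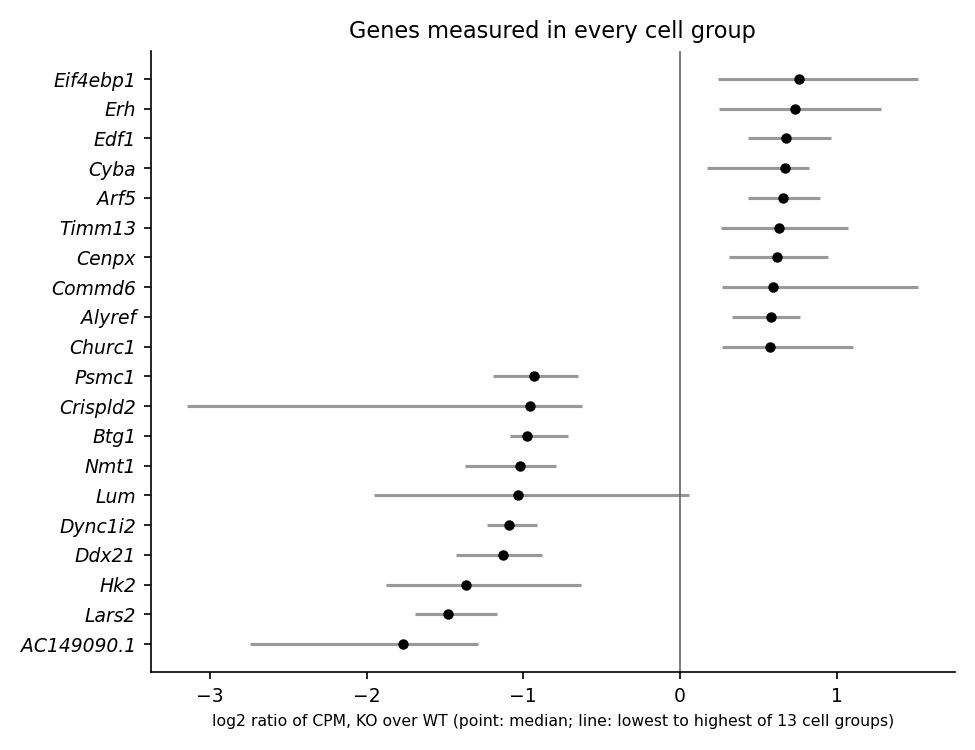
Log2 ratios of KO over WT (horizontal axis) of the 10 highest and the 10 lowest genes by median over 13 cell groups, among genes with at least 100 UMIs in each group, with points for medians and lines from the lowest to the highest group. Among these, Eif4ebp1 stood highest at a median of 0.76 and AC149090.1 lowest at -1.77, while Snhg9 and AC160336.1 had fewer UMIs in some groups and are not drawn.

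Basement membrane and integrin genes were lower in the KO library in each of the 4 classes, at -0.25, -0.32, -0.28 and -0.27. Across genes, ratios fell with transcript length in these classes, at a Spearman's rho of -0.22, -0.25, -0.3 and -0.35. Only the respiratory chain list was also matched on length, so the medians of other lists, here and above, may hold this trend. EGF and IGF pathway genes stood at -0.24, -0.18, -0.28 and -0.25, with Egfr at 36.2 against 62.8 CPM in luminal progenitors. Immediate early genes, which tissue digestion induces, stood at -0.02, 0.20, -0.04 and 0.01, with Fos at 949 against 673 CPM in luminal progenitors and 639 against 869 CPM in fibroblasts. Heat shock genes stood at -0.02, -0.02, -0.14 and -0.17, and glycolysis genes at 0.09, 0.03, 0.07 and 0.02, with the hexokinase gene Hk2 lowest of its list in each class. Wnt pathway genes stood at -0.09, -0.09, 0.04 and -0.04. Relative to the other classes, basement membrane medians turned to 0.16, 0.11 and 0.11 in basal, hormone-sensing and fibroblast cells, and EGF and IGF medians to 0.24 and 0.09 in basal and hormone-sensing cells.

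Cells with UMIs of at least 2 G2/M genes, after thinning to 2000 UMIs per cell, made up 4.82% (4.10 to 5.62%) of KO and 6.63% (5.78 to 7.58%) of WT epithelial cells. In basal cells the shares were 8.01% (5.9 to 10.6%) and 9.91% (8.02 to 12.1%). This class includes cluster 25 (47 KO and 90 WT cells), with the cycle genes Ccnb1, Cdc20 and Ube2c among its leading genes. Serpinb11, Lbhd2 and Shisa8, leading genes of cluster 6, were among them too, so the basal values may include dividing cells like cluster 6. Cluster 6 itself had shares of 0.964% (0.263 to 2.45%) and 1.76% (0.847 to 3.21%). In luminal progenitors they were 0.459% (0.0556 to 1.65%) and 0.826% (0.1 to 2.95%), in hormone-sensing cells 0.563% (0.227 to 1.16%) and 0.857% (0.371 to 1.68%), and in fibroblasts 0 of 4343 KO cells and 0.0851% (0.0176 to 0.249%) of WT cells. Thinning left out 22 KO and 86 WT epithelial cells. Without thinning, the epithelial shares were 18.2% (16.9 to 19.6%) and 18.5% (17.2 to 19.9%), a difference of -0.34 points, and with at least 3 genes and no thinning 9.54% and 11.4%, so the size of the difference rests on both limits. With at least 3 genes after thinning, they were 3.95% and 4.99%, basal cells stood at 6.94% and 7.21%, luminal progenitors turned to 0.229% of KO and 0% of WT cells, and hormone-sensing cells held none in either library.

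In T cells, the cytokine gene Il17a was higher in the KO library at 75.9 (68.2 to 84.2) against 30.1 (23.2 to 38.3) CPM, with 66.2% of its 65 WT UMIs in 5 cells, as was the lipid droplet gene Hilpda at 122 against 51.3 CPM. Cxcl10 stood at 77.4 against 33.3 CPM, with 1 cell holding 37.7% of the KO UMIs. With cells classed one by one, the ratio of Hilpda moved from 1.24 to 0.02 and that of Cxcl10 turned from 1.19 to -1.32, and after thinning that of Il17a was 0.70 in place of 1.31. Olfr1369-ps1 was lower at 23.7 against 116 CPM, with 59.8% of its WT UMIs in 5 cells. In B cells, Bcl2a1d, Commd6 and Coa3 were higher at 57.2 against 18.8 CPM, 67.9 against 23 CPM and 71.3 against 29.3 CPM, with 72.2% of the 18 WT UMIs of Bcl2a1d in 5 cells. The low values of Cxcl13 (6 UMIs in 390 KO cells), Iglc2 and Jchain came from few WT cells: 1 cell held 98.6%, 92.4% and 44.7% of their WT UMIs, and with cells classed one by one Iglc2 turned from -3.29 to 0.69 and Jchain from -2.90 to 2.72. The TMM factor of the KO over the WT library was -0.22 in T cells, -0.13 in B cells and -0.14 in dendritic cells on the log2 scale, so ratios scaled by TMM lie higher by that much there.

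In macrophages, the osteopontin gene Spp1 was higher in the KO library at 646 (619 to 673) against 64 (56.5 to 72.2) CPM and the glycoprotein gene Gpnmb at 76.8 (67.9 to 86.6) against 18.5 (14.6 to 23.2) CPM, although 1 cell held 61.6% and 57.8% of their KO UMIs. Luminal keratin and junction genes, led by Krt19, were higher there too, at a median of 1.08 (0.95 to 1.20), and so were hormone receptor genes, at 0.30 (0.04 to 0.50), so RNA of epithelial cells differed in this class. In T cells and vascular endothelial cells the keratin and junction list was lower, at -1.61 (-1.83 to -1.30) and -1.80 (-2.07 to -1.45). The mean over cells gave Spp1 a log2 ratio of 1.94 in place of 3.31. Syngr1 stood at 61.3 against 16.4 CPM. The endothelin gene Edn1 was lower at 46.1 (39.3 to 53.8) against 267 (252 to 283) CPM, with 52.8% of its KO and 43.8% of its WT UMIs in 5 cells. The actin-bundling gene Fscn1 was lower too, at 15.5 against 87.8 CPM, with 5 of 212 WT cells holding 65.8% of its WT UMIs. In dendritic cells, Atp1b1 was higher at 53.4 (47.6 to 59.9) against 12.8 (9.72 to 16.6) CPM, with 43.8% of its KO UMIs in 5 cells and the hormone receptor list, led by Prlr, also higher there at 0.92 (0.65 to 1.21). In this class 1 cell held 50% of the KO UMIs of the neutrophil gene Retnlg, 81.2% of those of the antibody gene Igkc, 98.8% of the WT UMIs of Iglc1 and 66.8% of those of Serpinb2. In pericytes or smooth muscle cells, Mnd1, Higd1b and Sept4 were higher at 65.5 against 18.7 CPM, 80.9 against 24.5 CPM and 72.7 against 23.2 CPM, and Nol4l was lower at 15.4 against 57.1 CPM, with 5 cells holding 90.4% of its WT and 93.3% of its KO UMIs. The pericyte or smooth muscle class left out cluster 24, in which Higd1b and Sept4 were among the leading genes. With cells classed one by one, Retnlg turned from 5.35 to -0.02 and Igkc from 2.63 to -0.30 in dendritic cells.

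In vascular endothelial cells, Glycam1, a ligand of L-selectin made by high endothelial venules of lymph nodes, stood at 8781 (8676 to 8886) against 0.857 (0.177 to 2.5) CPM, all KO UMIs being in 16 of 328 cells and 93.5% of them in 5. The chemokine gene Ccl21a stood at 1599 (1554 to 1644) against 37.7 (31.5 to 44.7) CPM, from 18 KO and 2 WT cells, 5 KO cells holding 64.2% of the KO UMIs. Serpina1e had 161 UMIs in the KO library and 0 in the WT library, at least 61.6-fold higher, but from 8 KO cells, 5 of which held 96.3% of the UMIs. The urokinase gene Plau was lower at 23 (17.9 to 29) against 79.1 (70.0 to 89) CPM. With doublets kept, the log2 ratio of Glycam1 was 3.52 in place of 12.21.

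In cluster 6, Tcim was higher in the KO library at 132 (124 to 139.6) against 71.2 (66.3 to 76.5) CPM, as in basal cells, and so were the hyaluronan synthase gene Has2 at 51.1 against 27.5 CPM and Phpt1 at 71.8 against 40.6 CPM. In cluster 7, Ramp1, Rnaset2a and Rnaset2b were higher at 64.8 against 31.6 CPM, 57.8 against 28.2 CPM and 57.5 against 29.1 CPM, as in hormone-sensing cells, and the kinetochore gene Cenpf was lower at 12.9 against 54.5 CPM, with 64.4% of its WT UMIs in 5 cells. In cluster 20, Nupr1, Ccdc71l and Eif4ebp1 were higher at 322 against 151 CPM, 51.6 against 24.8 CPM and 123 against 63.9 CPM. Its chemokine gene Ccl5 stood at 0.827 against 249 CPM, with 3 KO UMIs and 99% of the WT UMIs in 1 cell.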

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

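The settings that left out cluster 30 or the clusters of 1 library, that added cluster 6 to basal cells or cluster 10 to fibroblasts, and that took ratios relative to the other classes were chosen after seeing the data, the others before. No paired analysis was possible because each genotype has 1 library, and no test was made. Over all settings, 763 of 894 recomputed list medians kept their direction, and of the 131 that turned, 37 had a counting interval clear of 0 and 94 had one that spanned it. Of 902 ratios of named genes 878 kept their direction, as did 53 of 55 ratios of shares, all 5 Gpm6a values and 16 of 18 cell-cycle differences, where with at least 3 genes luminal progenitors turned and hormone-sensing cells went to 0. The named genes had been chosen as the highest and lowest ratios in these data. Their kept direction was therefore largely set by that choice. Without counting as reversed, 245 list medians and 323 gene ratios left their counting interval. Depth limits genes of low level and classes of few cells most, where counting intervals were wide. For each value below the cause was not tested.

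For Gpm6a, the log2 ratio (-1.27) was -2.66 with a pseudocount of 0.1 CPM, -0.45 without cluster 30 and -0.41 without the clusters of 1 library. The ratio of basal shares of KO over WT (0.584) was 0.685 with all deposited barcodes, 0.673 at most 5% mitochondrial UMIs, 0.712 with doublets kept and 0.495 with doublets removed up to the expected rate. It was 0.667 at Leiden resolution 0.5, 0.669 at resolution 2, 0.779 with each library clustered alone and 0.665 with cluster 6 added. The luminal progenitor ratio (1.65) turned to 0.857 with each library clustered alone, where the hormone-sensing ratio (1.22) was 1.41 and the T cell ratio (2.5) 5.43. Progenitors then numbered 447 KO and 563 WT cells in place of 440 and 250, and T cells 760 and 138 in place of 712 and 281. These 2 ratios may thus compare classes that do not hold like cells in both libraries. With doublets removed up to the expected rate, the hormone-sensing ratio was 1.37. The fibroblast ratio (1.19) turned to 0.967 at most 5% mitochondrial UMIs and was 1.11 with all barcodes, 1.07 with cells classed one by one, 1.06 without the clusters of 1 library and 1.02 with cluster 10 added. With the mitochondrial limit, the class held 4575 KO and 4338 WT cells in place of 4578 and 3802. Its WT gain thus came from clustering and naming anew, and not from the filter itself.

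Ratios relative to the other classes, whose reference is within reach of free RNA for genes that few classes express, turned most often: computed for all 365 list medians and 233 genes of the 13 groups, 64 and 27 of them reversed, and among those the text reports, 22 of 112 list medians and 18 of 134 genes. The respiratory chain list turned to -0.034 in luminal progenitors and -0.039 in hormone-sensing cells and was 0.049 in basal cells and 0.12 in fibroblasts. In basal cells, basement membrane genes turned to 0.16, NF-kB genes to 0.17, EGF and IGF genes to 0.24, TGF-beta and BMP genes to 0.12 and ribosomal protein genes to -0.21, and G2/M genes were -0.31. Milk genes in luminal progenitors turned to 0.10. In hormone-sensing cells, basement membrane genes turned to 0.11, luminal keratins and junctions to 0.071, EGF and IGF genes to 0.088, ribosomal protein genes to -0.084 and mitochondrially encoded genes to 0.0398, and NF-kB genes were -0.27. In fibroblasts, basement membrane genes turned to 0.11, stem-cell genes to 0.13, Notch genes to 0.051, mesenchymal transition genes to 0.17 and NF-kB genes to 0.10. There, TGF-beta and BMP genes turned to 0.15, collagen and matrix genes to 0.24 (Col1a1 in basal cells stood at 45.1 against 83.8 CPM), adipogenic genes to 0.014 and mitochondrially encoded genes to 0.19.

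On this relative scale, Tsix turned to 0.13 in basal cells, 0.28 in cluster 6 and 0.0497 in cluster 7, and Slc15a2 to -2.12 in luminal progenitors. Rnaset2b (-0.18), Bst2 (-0.079), AC149090.1 (0.20) and Lars2 (0.17) turned in hormone-sensing cells. Nupr1 (-0.039), Snhg9 (0.18), AC160336.1 (0.43), Lars2 (0.17) and Ddx21 (0.14) turned in fibroblasts, as did Dync1i2 (0.19), Taf1d (0.033) and Smpd3 (0.18). Snhg9 also turned in cluster 20 (0.33) and in pericytes or smooth muscle cells (0.33).

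With cells classed one by one, MHC class II genes turned to -1.65 in luminal progenitors, where Cxcl10 turned to -0.21, interferon-stimulated genes were 0.16 and respiratory chain genes 0.21. Basal keratins in hormone-sensing cells turned to -0.79 and TGF-beta and BMP genes in basal cells to 0.044, where respiratory chain genes were 0.15. Iglc2 (0.69) and Jchain (2.72) turned in B cells, Cxcl10 (-1.32) in T cells, and Retnlg (-0.024) and Igkc (-0.30) in dendritic cells. Keeping doublets turned basal keratins to -1.35 and MHC class II genes to -0.047 in hormone-sensing cells, and respiratory chain genes were 0.27 there and 0.23 in basal cells.

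Thinning to 2000 UMIs turned G1/S genes to 0.14, NF-kB genes to 0.071 and TGF-beta and BMP genes to 0.025 in basal cells. With it, G2/M genes were -0.071 and respiratory chain genes 0.34 in basal cells, and respiratory chain genes 0.38 in fibroblasts. The mean over cells turned basal keratins to -0.024, NF-kB genes to 0.047 and TGF-beta and BMP genes to 0.00095 in basal cells, and G2/M genes were -0.27 there. Respiratory chain genes by that mean were 0.32 in basal cells and 0.39 in fibroblasts. TMM scaling turned immediate early genes in hormone-sensing cells to 0.031, and in fibroblasts TGF-beta and BMP genes to 0.015 and adipogenic genes to 0.026. Under TMM, respiratory chain genes were 0.32 in hormone-sensing cells and 0.51 in fibroblasts. A pseudocount of 5 CPM gave interferon-stimulated genes 0.47 in luminal progenitors and NF-kB genes -0.35 in hormone-sensing cells, and a minimum of 100 UMIs turned mesenchymal transition genes to 0.022 in basal cells.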

Other observations

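The tests of loss of Gpm6a within the cell, of cluster 18 alone and of chance doublets were chosen after the results had been seen, as were the genes of the next paragraph.

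Further genes were picked for their distance from the median ratio of the other classes. For these genes of 1 or few classes that reference is not printed, because it is within reach of free RNA: the basal gene Krt14 stood at 6.77 against 40.7 CPM in T cells. In basal cells the protease inhibitor gene Slpi was higher in the KO library at 1816 against 990.4 CPM, and the tropomyosin gene Tpm2 at 3097 against 1744 CPM. In hormone-sensing cells the uroplakin gene Upk3a was higher at 1648 against 1276 CPM and Dmbt1, a mucosal defence gene, lower at 155 against 235 CPM, while Tpm2 and the transcription factor gene Sox4 stood at log2 ratios of 0.87 and 0.50, close to 0.83 and 0.51 in basal cells. In luminal progenitors the homeobox gene Barx2 was higher at 126 against 92 CPM and the adhesion gene Ceacam1 lower at 389 against 535 CPM. In fibroblasts the IL-33 receptor gene Il1rl1 was higher at 122 against 83.1 CPM and Igfbp2 at 129 against 96.7 CPM, and the transcription factor gene Klf2 lower at 205 against 284 CPM.

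Over 2821 genes measured in all 13 cell groups, the log2 ratios of pairs of groups were correlated across genes at a median Spearman's rho of 0.64 (0.45 to 0.87 over 78 pairs), where genes are not independent replicates. Among venule genes in endothelial cells, Fut7 (71 against 0 UMIs), Chst4 (17 against 0), Gcnt1 (37 against 3) and Enpp2 (566 against 321) were higher in the KO library, and Madcam1 (32 against 71) and Parm1 (50 against 79) lower. Ubd, a ubiquitin-like gene seen beside Glycam1 and Ccl21a, stood at 450 against 42 UMIs. Of the nuclear RNAs, Malat1 and Neat1 were lower in the KO library in all 13 groups, with Malat1 in basal cells at 13257 against 21745 CPM, while Xist was at 1005 against 1078 CPM there.

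The first pattern weighed is the shift shared by cell types: the respiratory chain list higher, and Snhg9, Tsix and Lars2 lower, in the KO library in each group compared. Ranges in brackets in this paragraph run from the lowest to the highest cell group and are not intervals. The tables argue against scaling, since the list's median over 13 groups stayed at 0.31 (0.24 to 0.55) with TMM factors. For an effect confined to cells that express Gpm6a, the values go the other way but do not exclude it, since the gene is near the floor and the test was chosen on groups already known to stand above 0: the median was 0.27 (0.15 to 0.39) in the 5 groups without a Gpm6a UMI, whose WT limits run from 0.277 (cluster 6) to 3.14 CPM (B cells), and 0.25 in vascular endothelial cells, which held the most. Transcript length may account for much of the list's shift: beside random lists matched on length and level, 2 of 13 groups stayed in the top 2.5% (percentiles 99.75 in fibroblasts and 98.96 in macrophages), and matched lists themselves stood at a median of 0.16. More nuclear RNA in the WT library stays open, with a median of -0.47 (-0.71 to -0.11) for 5 nuclear RNAs that did not move together. A difference between genotypes that acts on all cells was not tested.

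The second pattern is that cell populations differed between the libraries. For cluster 18 the tables argue against a shared cell type split by a library shift that leaves its leading genes in place. At the level of its own cells, 5 KO against 300 WT cells (1.67%) held these genes. A shift that lowered the genes, which were chosen from these WT cells, is not excluded. Over the 5 clusters of 1 library the figure was 95.1%, which met the limit set for such a split but decides nothing, because the limits of clusters 27, 30 and 31, with 71, 57 and 29 WT cells, let 2119, 10330 and 391 WT cells pass. For these 3 the test is void, and a split stays open there and for cluster 10 (42.8%, with 1382 WT cells passing for 647 in it). Lymph-node tissue in the KO sample could bring lymphocytes and venule cells together and stays open too. The 6 venule genes, with 773 KO and 474 WT UMIs, had a log2 ratio of 0.90 (0.74 to 1.07), between the limits set. Enpp2, also a leading gene of fibroblast cluster 2, held 566 of the KO and 321 of the WT UMIs and so weighs most. Of the others, Fut7, Chst4 and Gcnt1 were higher in the KO library, and Madcam1 and Parm1 lower. A difference between genotypes in these populations was not tested.

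The third pattern is cluster 7, in which the progenitor genes Aldh1a3 and Elf5 and hormone-sensing genes were found together, in 451 KO and 317 WT cells. The tables argue against chance doublets, which would make up 1.94% of it (14.9 cells expected over both libraries). Cells of both types that stayed attached through digestion are consistent with its profile: at most 0.0355% of genes of at least 50 CPM were more than 2-fold above both source classes (Hbb-bs of 2818 genes in the KO library, Cenpf of 2892 in the WT library). Its median depth was 1.11 (KO) and 1.06 (WT) times the sum of both source medians, and a mix of the classes followed it across genes at a rho of 0.984 and 0.988. An intermediate cell type would mix these genes too and stays open, as does a difference between genotypes, which was not tested.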
